A study of Arabidopsis thaliana with 6 samples.

How the data were processed

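Total RNA from Col-0 seedlings of 7 days was labelled with biotin and hybridised to 1-colour Affymetrix ATH1 arrays, per the labels, with 6 arrays in 3 groups of 2. Groups and replicate numbers were taken from the sample titles, and the series design describes the replicates as biological. The authors deposited 1 table of expression values for 22810 probe sets; its unit is log2, read from the range of 2.22 to 14.23 and from the use of RMA, which the submitters' processing notes name together with limma. The version of RMA, the chip definition, the probe-level settings and the authors' use of limma are not given in the sources used here, and no scanner values were used here to set the table against, so the log2 scale is inferred. The median over probe sets was 5.93 on each dark array and 6.01 to 6.07 on the other 4. The arrays give no counts, so there is no depth, and the number of arrays limits the precision.

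The 64 array control probe sets were set aside and the remaining 22746 were tested, with no filter on dim signals. Gene names came from the platform's annotation table, updated by gene identifier through the RefSeq gene table of the TAIR10.1 assembly; 13436 probe sets matched a locus there with a gene span. Of the tested probe sets, 13513 (59.4%) name 1 gene, 503 name several and 8730 are unnamed here; genes were named only from the first kind, and where several probe sets named a gene the one with the highest mean over all arrays stood for it, which left 13356 genes. Counts of calls are over all tested probe sets. No coordinates are given, since no source used here names a genome build for the arrays. HY5, PIF1, PIF3, CAT1, CAT2, CAT3, APX1, APX2, ZAT12, and the LHCB1 and RBCS genes were to be named in any case but have no single-gene probe set in the table used, and are not analysed here.

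Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 6 arrays, 3 contrasts, 3 residual and 5.84 prior degrees of freedom), 2-sided, and called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Values are given as log2 differences ± their standard error from the fit, and group levels as mean ± SD of 2 arrays. The fit, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap between the groups, the 3 called members of each fixed list with the largest change (or 2 as values where none was called), HYH and the genes above where measured, and the 5 genes with the largest summed change in each of the 4 combinations of direction for the overlap. STZ, PRXR1 and the genes named under other observations lie outside it and were chosen after their values were seen.

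The 25 fixed gene lists held 529 genes, of which 111 were measured by a single-gene probe set, and none of 8 root endodermis genes was. Measured were 8 of 42 antioxidant enzyme, 5 of 31 photosystem and electron transport, and 3 of 19 light-harvesting antenna genes. Coverage was highest for the class III peroxidases, at 15 of 23. Counts for a list therefore describe its measured members and not the whole class. Lists with at least 5 measured genes, 11 in all, were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over those lists, with an estimated correlation and fry beside it. No list was called with an estimated correlation in any comparison. That test rests on the 3 residual degrees of freedom and had little power. Failing it therefore does not show that correlation between genes made a call. In light the auxin response, heat shock and flavonoid lists had estimated correlations of -0.0035, -0.014 and -0.020. These lie under the preset value, yet each adjusted p with an estimated correlation was 0.144. The other lists called in light had estimates above the preset value. They were 0.028 for oxidative stress markers, 0.10 for photosystem and electron transport, 0.11 for antioxidant enzymes and 0.12 for class III peroxidases. Chlorophyll biosynthesis had 0.43 and the dark-induced and sugar starvation genes 0.62. For these lists, in every comparison, the preset value may make the camera p-values too small. By fry, which asks whether the genes of a list move one way on balance, 1 list passed with H2O2, the heat shock proteins (adjusted p = 0.0412). In light every tested list passed fry but the glutathione S-transferases (adjusted p = 0.777). Between light and H2O2 all passed but these (0.391) and the expansins (0.0897). Counts adjusted over the list alone are given where they differ from those over all probe sets.

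The steps were tested on simulated data made from each probe set's mean over all arrays and normal noise of the fitted spread, with 50 probe sets changed by each of 4 sizes. For H2O2 against dark, 12%, 98%, 100% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale were called, and 18 unchanged probe sets were called. For light against dark the shares were 4%, 94%, 100% and 100%, with 15 unchanged ones. The changed probe sets called numbered 6, 49, 50 and 50 with H2O2 and 2, 47, 50 and 50 in light. In both, the unchanged ones were a larger share of the calls than the threshold on adjusted p aims at. The simulation therefore does not show that false calls are held to that threshold. Far fewer probe sets changed there than were called in the data, which makes the adjusted threshold stricter. The shares for changes of 0.5 are therefore lower than the data would give. Alternatives were the replicate number as a block, a trended and robust variance prior, cyclic loess normalization, centring on the 18 hybridisation control probe sets, leaving out the lowest 40% of probe sets by mean, fitting the compared groups alone, leaving out each array, a threshold of 0.01, 1 probe set per gene, an estimated correlation and the mean of a gene's probe sets. Leaving out an array of a compared group leaves a lone array there, so calls can end from lost power alone. The bound for dim genes, removal of a trend on gene span, and leaving out each array for the gene groups under other observations, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.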

Results

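Transcript levels were measured in seedlings of Arabidopsis thaliana, accession Col-0, on 6 Affymetrix ATH1 arrays, with 2 biological replicates for each of 3 growth conditions. Seedlings grew for 7 days in the dark, in the dark with 5 mM hydrogen peroxide (H2O2), or under a daily cycle of 16 h of light and 8 h of dark. Per the series description, darkness was meant to lower the H2O2 that seedlings make themselves, so the dark group is the background for both added H2O2 and light. Values are log2 expression, so that a difference of 1 is a 2-fold change, and the number of arrays limits the precision: the median standard error of a difference was 0.15. A gene is called dim in a group where its mean lies under 5.16, the bound of the lowest 40% of probe sets by their mean over all arrays. The size and rank of a difference from or to a dim level are uncertain. Replicate arrays correlated at r = 0.993 in the dark, 0.995 with H2O2 and 0.993 in light across all probe sets. Pairs of a dark and an H2O2 array correlated at 0.974 to 0.979, and pairs of a dark and a light array at 0.898 to 0.901. The difference between the 3-prime and 5-prime signal of 6 pairs of control probe sets was 1.64 ± 0.17 (SD, n = 2) in the dark, 1.65 ± 0.11 with H2O2 and 1.45 ± 0.18 in light. The bacterial hybridisation controls were spiked in during processing and had a median log2 signal of 9.80 ± 0.47 in the dark, 9.02 ± 0.088 with H2O2 and 9.11 ± 0.61 in light. The Bacillus control probe sets, which were not used for centring, had 7.82 ± 0.66, 6.55 ± 0.098 and 6.26 ± 0.68 in the same groups.

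The comparison of H2O2 with dark asks which transcripts respond to added H2O2 without light. AT3G05900 rose by 3.62 ± 0.14 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 3.3e-05). M17, a late embryogenesis abundant protein gene, rose by 3.58 ± 0.58 (adjusted p = 0.00344), and PAP85, a vicilin-like seed storage protein gene, rose by 2.76 ± 0.41. AT2G28490, on the fixed list of seed storage and oil body genes, rose by 2.42 ± 0.28, from 3.88 ± 0.024 (SD) in the dark to 6.30 ± 0.15 with H2O2. TPLATE, which acts in endocytosis, rose by 2.35 ± 0.19, and MED19A, a subunit of the Mediator complex, by 2.49 ± 0.28. The other 4 of the 10 largest rises were AT2G02160, AT3G57470, AT1G04780 and AT5G03660, with log2 changes of 2.65, 2.51, 2.42 and 2.39. All of these 10 but TPLATE are dim in the dark, so their sizes and order are uncertain. AT3G55790 had the largest fall, a log2 change of -4.05 ± 0.29 (adjusted p = 0.000176), from 10.02 ± 0.12 in the dark to 5.96 ± 0.76 with H2O2. AT1G26240 followed with -2.88 ± 0.23, and the other 8 of the 10 largest falls, AT3G16670, AT4G22640, AT3G60270, AT3G59480, AT3G29970, AT1G47400, AT2G23270 and AT3G05730, lay between -2.54 and -2.25. AT1G26240, AT4G22640, AT3G60270 and AT3G29970 are dim with H2O2, with the same limit. The fall of AT3G05730 was not called without dark replicate 1 (adjusted p = 0.0562).

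Of 5 lists of oxidative stress and related genes, class III peroxidases and heat shock proteins were called with H2O2, and neither with an estimated correlation. Of 8 antioxidant enzyme genes measured, GR1, a glutathione reductase gene, rose by 1.07 ± 0.13 (adjusted p = 0.000998) and 7 were not called (camera adjusted p = 0.581). Of 8 oxidative stress marker genes, AT2G21640 rose by 0.57 ± 0.15, while AT1G57630 fell by 1.42 ± 0.17 and AT1G05340 fell by 0.56 ± 0.13; adjusted over the list alone, 1 was higher and 5 were lower. STZ, a zinc finger transcription factor gene on that list, had a log2 change of -1.58 ± 0.57 and was not called (adjusted p = 0.0834). The list lay lower than other genes without passing the test (camera adjusted p = 0.056), at a median log2 change of -0.53 that turned to 0.25 with the arrays centred on the hybridisation controls; AT1G05340 turned to 0.22. Of 15 class III peroxidase genes, 6 fell and 2 rose (adjusted over the list alone, 6 and 3), and the list was called lower (camera adjusted p = 0.0487; adjusted p = 0.668 with an estimated correlation), with a median of -0.44 that turned to 0.34 with the same centring. The falls included AT4G26010 at -1.64 ± 0.23, AT1G30870 at -1.50 ± 0.24 and AT5G39580 at -1.26 ± 0.38; the rises were AT2G37130 at 0.55 ± 0.15 and PRXR1 at 0.60 ± 0.13. Of 8 glutathione S-transferase genes, GSTU20 fell by 1.43 ± 0.34, GSTU28 fell by 0.92 ± 0.22 and 6 were not called (camera adjusted p = 0.678; the median of -0.037 turned to 0.74 with centring). Of 6 heat shock protein genes, 3 rose, and the list was called higher (camera adjusted p = 0.0487), with adjusted p = 0.581 with an estimated correlation. The class III peroxidase list was not called without dark replicate 1 (adjusted p = 0.0879) or H2O2 replicate 2 (0.113), nor the heat shock list without dark replicate 2 (0.138), without H2O2 replicate 2 (0.113) or with centring on the hybridisation controls (0.0607). The heat shock rises were AT5G51440, a small heat shock protein gene, at 1.09 ± 0.13, AT5G48570 at 0.99 ± 0.16 and AT1G53540, another small heat shock protein gene, at 0.44 ± 0.13. All 3 are dim in the dark, and AT1G57630 is dim with H2O2. Left out in turn, each of the 4 dark and H2O2 arrays ended the calls of AT2G21640 (adjusted p 0.0601 to 0.151), AT1G05340 (0.0592 to 0.106), AT5G39580 (0.124 to 0.204), AT2G37130 (0.087 to 0.164) and AT1G53540 (0.112 to 0.15). GSTU20 was not called without dark replicate 1 or 2 (0.0594 and 0.0916), nor GSTU28 without dark replicate 1, dark replicate 2 or H2O2 replicate 1 (0.0516 to 0.143).

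The 3 measured root hair genes all fell with H2O2, with a median log2 change of -1.46: EXPA7 and EXPA18, expansin genes of root hairs, by 1.46 ± 0.19 and 1.46 ± 0.24, and AT4G26010 as given. With the arrays centred on the hybridisation controls the median was -0.68 and none of the 3 was called. EXPA7 and EXPA18 are dim with H2O2. EXPA20 also fell among 8 expansin genes, at -0.61 ± 0.15, which turned to 0.16 with centring on the hybridisation controls, and 5 were not called; adjusted over the list alone, 3 were lower and 1 was higher. The expansin list had a median of -0.23, which turned to 0.55 with centring on the hybridisation controls, and a camera adjusted p of 0.138. The 3 measured seed storage and oil body genes all rose, with OLEO3, an oleosin gene, at 0.54 ± 0.14. COR47, a dehydrin gene, rose by 1.82 ± 0.21, the single call among 3 genes of abscisic acid and dehydration. Of 6 dark-induced and sugar starvation genes, 3 rose (4 adjusted over the list alone; camera adjusted p = 0.138): MCCA at 1.05 ± 0.24 and MCCB at 0.59 ± 0.15, subunits of 3-methylcrotonyl-CoA carboxylase, and PPDK at 0.63 ± 0.17. AIM1, of peroxisomal beta-oxidation, rose by 0.75 ± 0.13, and SAG101, of disease resistance signalling and dim in the dark, by 0.58 ± 0.14. Without dark replicate 2, H2O2 replicate 1 or H2O2 replicate 2, MCCA (adjusted p 0.0524 to 0.125), MCCB (0.105 to 0.161), PPDK (0.102 to 0.174) and SAG101 (0.0607 to 0.137) were not called. OLEO3 was not called without dark replicate 1 or either H2O2 replicate (0.117 to 0.15), nor EXPA20 without either dark replicate or H2O2 replicate 2 (0.0806 to 0.152).

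HYH, a bZIP transcription factor gene of light signalling and dim in the dark, rose by 0.98 ± 0.15 with H2O2 in the dark (adjusted p = 0.00284), and FHL, of phytochrome A nuclear import, rose by 0.55 ± 0.16. Among photosynthesis genes, PSAN, a photosystem I subunit gene, rose by 0.57 ± 0.14, the single call of 5 photosystem and electron transport genes (camera adjusted p = 0.227). PRK, encoding phosphoribulokinase of the Calvin cycle, rose by 0.67 ± 0.14, the single call of 3 there (2 adjusted over the list alone). HEME2, of tetrapyrrole synthesis, rose by 0.49 ± 0.13, the single call of 7 chlorophyll biosynthesis genes (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.374). None of the 3 light-harvesting antenna genes was called, with -0.34 ± 0.15 for LHCB4.3 and 0.32 ± 0.14 for LHCB4.2. None of 7 flavonoid biosynthesis genes was called (camera adjusted p = 0.675), with 0.87 ± 0.28 for UGT78D1, nor any of 7 auxin response genes (camera adjusted p = 0.678), with -0.42 ± 0.14 for GH3.3. The 2 measured jasmonate genes, PDF1.2 at -0.39 ± 0.15 and THI2.1 at 0.27 ± 0.14, were not called, nor were SIR at 0.36 ± 0.13 and APS3 at -0.36 ± 0.15 of sulfate assimilation (1 higher and 1 lower adjusted over the list alone). GI of the circadian clock, PRL of cell division and BCAT4 of glucosinolate biosynthesis, the single measured gene of each list, had log2 changes of -0.034, 0.22 and 0.11 and were not called. The calls of PSAN (adjusted p 0.0541 to 0.128), HEME2 (0.076 to 0.117) and FHL (0.0838 to 0.174) ended when any of the 4 dark and H2O2 arrays was left out. PRK was not called without dark replicate 2 or either H2O2 replicate (0.069 to 0.0839).

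In all, limma called 4656 of 22746 probe sets with H2O2, 2795 higher and 1861 lower, at a median absolute log2 change of 0.73, and 1147 of them changed at least 2-fold. Without dark replicate 2, H2O2 replicate 1 or H2O2 replicate 2 the count was 2306, 2173 and 2135. Centring on the hybridisation controls moved the median of all genes by 0.78 against dark with H2O2 and by 0.69 in light. It left 2379 calls, 98.9% higher against 60.0% here. Fewer calls are partly built in, since this centring adds the replicate differences of the controls to every probe set. Of 11 lists tested, 2 were called; without dark replicate 1, dark replicate 2 or H2O2 replicate 2 the number was 1, 1 and 0, with an estimated correlation 0, and without the dimmest probe sets 0.

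Genes with longer spans were called higher with H2O2 more often: over 13436 probe sets with a gene span, rank correlation between span and log2 change was 0.269, against 0.124 in light. The share called higher rose from 1.78% in the shortest 10% of spans to 23.2% in the longest 10%, and the share called lower fell from 9.58% to 2.38%.

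**Figure D1:**
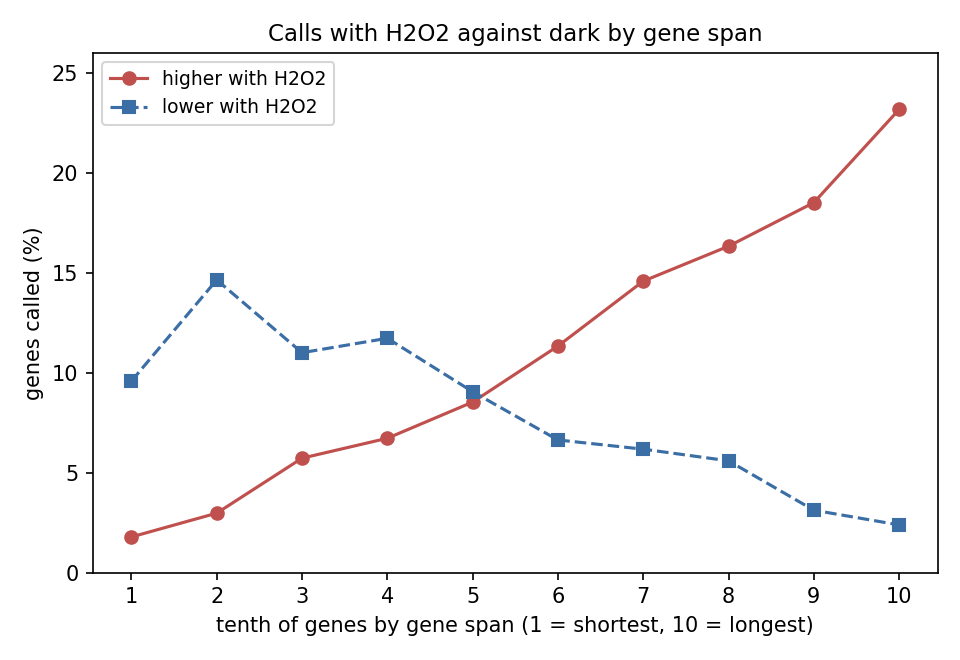
Percent of probe sets called with H2O2 against dark (vertical axis) in 10 equal groups of gene span from shortest to longest (horizontal axis), higher and lower calls apart.

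**Figure D2:**
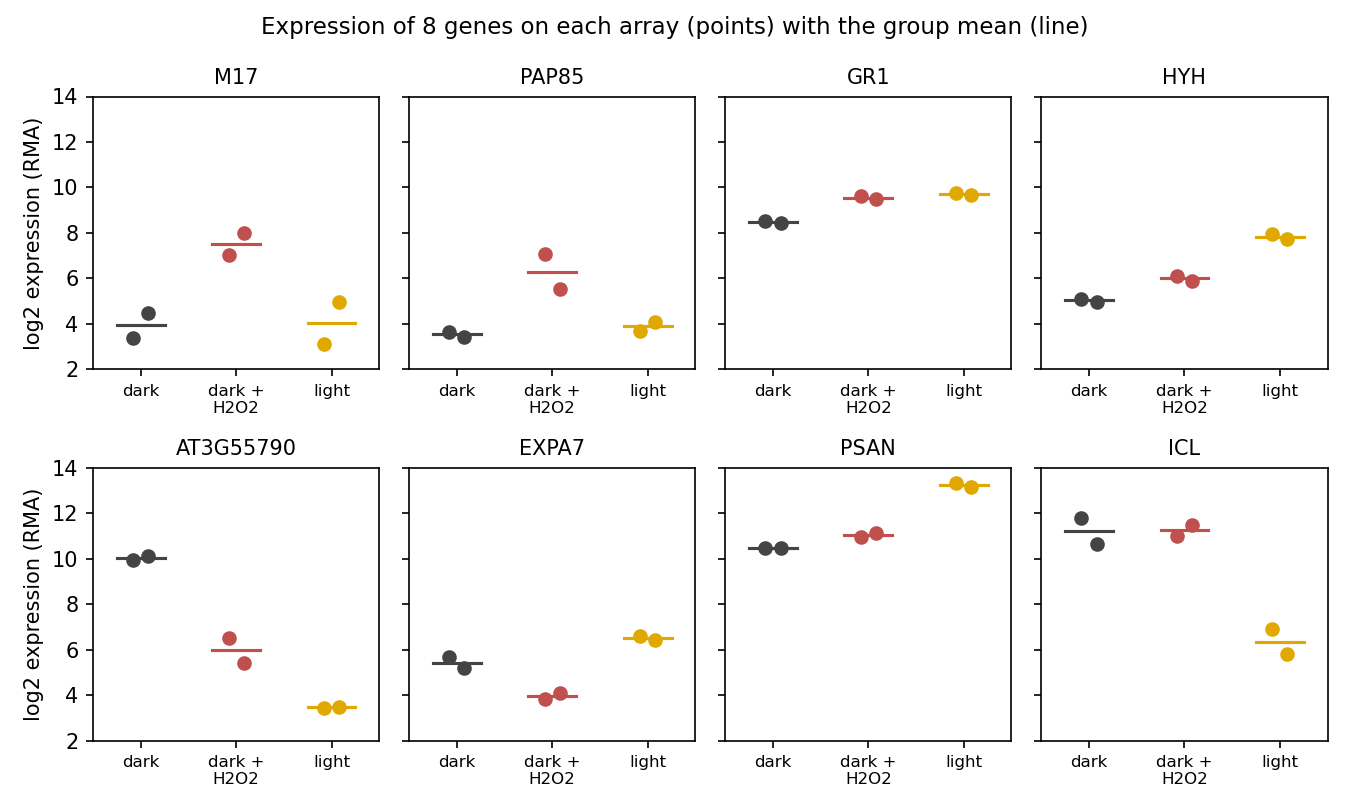
Log2 expression of 8 genes (vertical axis, RMA values) in the dark, dark with H2O2 and light groups (horizontal axis); points are the 2 arrays of a group and the line is their mean. M17 and PAP85 stand higher with H2O2 than in the other 2 groups, GR1 and HYH are higher with H2O2 and in light than in the dark, AT3G55790 is lower in both, EXPA7 is lower with H2O2 and higher in light, PSAN is highest in light, and ICL is lower in light.

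The comparison of light with dark asks which transcripts differ between light-grown and dark-grown seedlings. AT2G25510 was higher in light by 7.01 ± 0.34 on the log2 scale (adjusted p = 5.85e-07). ECS1 was higher by 6.66 ± 0.13 and THI2.2, a thionin gene, by 5.97 ± 0.14. The other 7 of the 10 largest rises, AT1G65490, AT1G65230, AT1G66100, AT1G51110, AT1G23130, AT3G48420 and AT2G29290, lay between 5.52 and 6.35. AT2G25510, THI2.2, AT1G65490, AT1G65230, AT1G66100, AT1G51110 and AT3G48420 are dim in the dark, so their exact sizes and order are uncertain. AT3G55790 was lowest in light against dark, at -6.56 ± 0.29 (adjusted p = 3.74e-07). ICL, isocitrate lyase of the glyoxylate cycle by which seedlings use stored oil, was lower at -4.87 ± 0.42, CCOAMT, a methyltransferase gene, at -5.38 ± 0.18, and COR27, a cold-regulated gene, at -5.18 ± 0.20. The other 6 of the 10 largest falls, AT1G19530, AT4G37220, AT5G39520, AT1G26250, AT2G47780 and AT5G44440, lay between -6.04 and -4.91. AT3G55790, CCOAMT, COR27, AT5G39520, AT1G26250, AT2G47780 and AT5G44440 are dim in light, with the same limit.

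Of the photosynthesis lists, 2 were tested, and the antenna and Calvin cycle lists, with 3 genes each, were too small. All 5 photosystem and electron transport genes were higher (camera adjusted p = 9.87e-05; adjusted p = 0.144 with an estimated correlation), among them PSAN at 2.75 ± 0.14, PSBY at 2.5 ± 0.13 and PSAE-1 at 2.44 ± 0.19. All 3 antenna genes were higher, LHCB4.2 at 1.92 ± 0.14, LHCB4.3 at 1.79 ± 0.15 and LHCB4.1 at 1.22 ± 0.14, as were all 3 Calvin cycle genes, SBPASE at 4.01 ± 0.15, PRK at 3.27 ± 0.14 and RCA, Rubisco activase, at 2.94 ± 0.19. Of 7 chlorophyll biosynthesis genes 6 were higher (camera adjusted p = 0.000378; adjusted p = 0.196 with an estimated correlation), including CHLI2, of magnesium chelatase, at 3.06 ± 0.15, HEME2 at 2.23 ± 0.13 and HEME1 at 1.99 ± 0.13. HYH, dim in the dark, was higher at 2.80 ± 0.15, and FHL, dim in light, was lower at -1.33 ± 0.16. Of 7 flavonoid biosynthesis genes 3 were higher (camera adjusted p = 0.0147; adjusted p = 0.144 with an estimated correlation), UGT78D1, dim in the dark, at 2.99 ± 0.28 and UGT78D2 at 2.58 ± 0.17, both flavonol glycosyltransferase genes, and CHIL at 2.63 ± 0.23.

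Antioxidant enzyme genes were higher in light, 7 of 8 (camera adjusted p = 0.000378; adjusted p = 0.144 with an estimated correlation), with TAPX, the thylakoid ascorbate peroxidase gene, at 3.25 ± 0.16, AT3G11630, a peroxiredoxin gene, at 1.96 ± 0.13 and GR1 at 1.24 ± 0.13. Oxidative stress marker genes were lower, 6 of 8 (camera adjusted p = 0.00468; adjusted p = 0.144 with an estimated correlation), with AT1G05340 at -3.10 ± 0.13, AT1G19020 at -2.77 ± 0.22 and AT1G57630, dim in light, at -2.21 ± 0.17. Of 6 heat shock protein genes 4 were higher (camera adjusted p = 0.0147; adjusted p = 0.144 with an estimated correlation), with AT5G48570 at 4.32 ± 0.16 and AT5G51440 at 1.15 ± 0.13, both dim in the dark. Of 15 class III peroxidase genes 8 were lower (9 adjusted over the list alone) and 3 higher (camera adjusted p = 0.0152; adjusted p = 0.25 with an estimated correlation), with AT5G39580 at -3.53 ± 0.38, AT2G37130 at -2.88 ± 0.15 and AT4G36430 at -2.68 ± 0.17. Glutathione S-transferase genes went both ways, 4 higher and 3 lower of 8 (camera adjusted p = 0.52), with GSTU20 at 3.13 ± 0.34, GSTU18 at 2.82 ± 0.22 and GSTU22 at -3.28 ± 0.16. Expansin genes also went both ways, 3 higher and 4 lower of 8 (camera adjusted p = 0.476), with EXPA20 at -1.98 ± 0.15, EXPA9 at -1.93 ± 0.15 and EXPA16, dim in light, at -1.55 ± 0.17, and the median of -0.47 turned to 0.22 with centring on the hybridisation controls. The 3 root hair genes were all higher in light, AT4G26010 at 1.32 ± 0.23, EXPA7 at 1.09 ± 0.19 and EXPA18 at 0.88 ± 0.24. EXPA18 was not called without dark replicate 2 or light replicate 1 (adjusted p = 0.0995 and 0.0748).

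All 7 auxin response genes were lower in light (camera adjusted p = 0.000641; adjusted p = 0.144 with an estimated correlation), with IAA20 at -3.28 ± 0.22, GH3.3 at -1.99 ± 0.14 and IAA29 at -1.84 ± 0.19. All 6 dark-induced and sugar starvation genes were lower (camera adjusted p = 0.00076; adjusted p = 0.231 with an estimated correlation), with IVD, of branched-chain amino acid breakdown, at -1.98 ± 0.14, AKINBETA1 at -1.75 ± 0.16 and MCCA at -1.54 ± 0.24. Of 3 beta-oxidation and glyoxylate cycle genes, SDP1, an oil body lipase gene, was lower at -0.95 ± 0.14 beside ICL, and AIM1 was higher at 0.65 ± 0.13. OLEO3 was lower at -2.60 ± 0.14, the single call of 3 seed storage and oil body genes. APS3 at 1.61 ± 0.15 and SIR at 0.85 ± 0.13, both measured genes of sulfate assimilation, were higher, as was BCAT4 of glucosinolate biosynthesis at 3.66 ± 0.30. COR47 at 1.21 ± 0.21 and COR15A at 0.97 ± 0.15 were higher among 3 genes of abscisic acid and dehydration. GRX480, a glutaredoxin gene, was lower at -1.38 ± 0.16 among 2 salicylic acid defence genes. PRL was higher at 0.59 ± 0.16, a call lost without dark replicate 1 or light replicate 2 (adjusted p = 0.0661 and 0.0756). Neither jasmonate gene nor GI was called. IAA20, IAA29, OLEO3 and GRX480 are dim in light and COR15A in both groups.

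In all, limma called 10920 probe sets in light against dark, 5241 higher and 5679 lower, and 5258 of them differed at least 2-fold. With the arrays centred on the hybridisation controls 5261 were called, 88.2% of them higher against 48.0% here. Of 11 lists, 9 were called, with an estimated correlation 0, and without the dimmest probe sets 6.

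The comparison of light with H2O2 asks how light-grown seedlings differ from dark-grown seedlings given H2O2. ECS1 was higher in light by 7.66 ± 0.13 on the log2 scale (adjusted p = 1.21e-08), AT2G25510 was higher by 7.53 ± 0.34, THI2.2 by 6.77 ± 0.14, and MSRB6, a methionine sulfoxide reductase gene, by 5.45 ± 0.23. The other 6 of the 10 largest differences, AT1G65490, AT1G23130, AT1G66100, AT1G22690, AT1G51110 and AT3G56290, lay between 5.43 and 6.65. ECS1, AT2G25510, THI2.2, MSRB6, AT1G23130, AT1G65490, AT1G66100, AT1G51110 and AT3G56290 are dim with H2O2, so exact sizes and ranks are uncertain here. AT1G19530 was lowest in light, at -6.0 ± 0.32, ICL was lower at -4.90 ± 0.42, ATPMEPCRD at -4.82 ± 0.13 and COR27 at -4.81 ± 0.20. The other 6, AT5G39520, AT5G44440, AT4G37220, AT2G47780, AT4G35720 and AT4G25580, lay between -5.46 and -4.77. COR27, AT5G39520, AT5G44440, AT2G47780, AT4G35720 and AT4G25580 are dim in light, with the same limit. GSTU20 was higher in light by 4.56 ± 0.34, AT3G16670 by 4.12 ± 0.24 and AT1G47400 by 4.02 ± 0.14.

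The root hair genes were higher in light than with H2O2, EXPA7 by 2.55 ± 0.19, EXPA18 by 2.34 ± 0.24 and AT4G26010 by 2.97 ± 0.23, and the seed storage and oil body genes were lower, OLEO3 at -3.14 ± 0.14, AT2G28490 at -2.49 ± 0.28 and PAP85 at -2.41 ± 0.41. EXPA7 and EXPA18 are dim with H2O2, and these 3 seed genes in light. The lists called with the preset correlation were photosystem and electron transport (5 of 5 higher, adjusted p = 1.29e-05; 0.153 as adjusted p with an estimated correlation), chlorophyll biosynthesis (6 higher and 1 lower of 7, adjusted p = 0.000157; adjusted p = 0.187 with an estimated correlation) and antioxidant enzymes (5 of 8 higher, adjusted p = 0.000157; adjusted p = 0.161 with an estimated correlation). Flavonoid biosynthesis was also called higher (3 of 7, 4 adjusted over the list alone, adjusted p = 0.00702; adjusted p = 0.161 with an estimated correlation). Auxin response (6 of 7 lower, 7 adjusted over the list alone, adjusted p = 0.000215; adjusted p = 0.153 with an estimated correlation), dark-induced and sugar starvation (6 of 6 lower, adjusted p = 9.97e-05; adjusted p = 0.187 with an estimated correlation) and oxidative stress markers (5 of 8 lower, adjusted p = 0.0215; adjusted p = 0.187 with an estimated correlation) were called lower. SBPASE was higher by 3.59 ± 0.15, TAPX by 2.85 ± 0.16 and HYH by 1.82 ± 0.15, while MCCA was lower at -2.59 ± 0.24 and IAA20, dim in light, at -3.43 ± 0.22. The difference for GR1 was 0.17 ± 0.13 and was not called (adjusted p = 0.365).

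In all, limma called 8981 probe sets between light and H2O2, 3968 higher and 5013 lower in light, 3988 of them at least 2-fold. With the arrays centred on the hybridisation controls 2576 were called, 54.4% of them higher against 44.2% here.

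The overlap of both responses asks how far added H2O2 and light change the same transcripts relative to darkness. AT3G05900, AT1G65230, AT5G16030, AT5G55220 and AT3G48420 were higher in both, with AT5G16030 at 2.01 ± 0.15 with H2O2 and 4.96 ± 0.15 in light, and AT5G55220 at 2.04 ± 0.14 and 4.70 ± 0.14. AT3G55790, AT1G26250, CCOAMT, AT3G18250 and AT2G23270 were lower in both, with AT1G26250 at -1.93 ± 0.23 and -5.43 ± 0.23, and CCOAMT at -1.52 ± 0.18 and -5.38 ± 0.18. UGT73B4, a glucosyltransferase gene, was higher with H2O2 at 1.90 ± 0.17 and lower in light at -1.63 ± 0.17, as were AT5G44440, AT4G35720, AT4G25580 and AT1G12080. ECS1 was lower with H2O2 at -1.0 ± 0.13 and higher in light, as were THI2.2, AT1G22690, AT2G29310 and AT5G38980. Dim in the dark are AT3G05900, AT1G65230, AT5G55220, AT3G48420 and THI2.2. ECS1, AT2G29310, THI2.2 and AT1G65230 are dim with H2O2, and AT3G55790, AT1G26250, CCOAMT, AT3G18250, AT2G23270, UGT73B4, AT5G44440, AT4G35720 and AT4G25580 in light. The order of these genes is therefore uncertain. The calls of AT5G44440 (adjusted p 0.0782 to 0.118) and AT2G29310 (0.0629 to 0.212) with H2O2 ended when any of the 4 dark and H2O2 arrays was left out. Other calls with H2O2 ended without some of these arrays: AT4G35720 (0.0962 to 0.142), AT1G12080 (0.0688 to 0.115) and AT5G38980 (0.0675 to 0.222) without dark replicate 2 or either H2O2 replicate, AT4G25580 (0.0999 and 0.123) without dark replicate 2 or H2O2 replicate 2, AT1G22690 (0.0605 to 0.267) without either dark replicate or H2O2 replicate 2, AT3G48420 (0.0506 to 0.075) without dark replicate 1 or either H2O2 replicate, and THI2.2 (0.054) without H2O2 replicate 2. With the arrays centred on the hybridisation controls, the H2O2 changes of AT1G22690, AT2G29310 and AT5G38980 turned to 0.13, 0.17 and 0.12.

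Of the 4656 probe sets called with H2O2, 3290 (70.7%) were called in light in the same direction, 345 (7.41%) in the opposite direction and 1021 (21.9%) were not called in light. Both higher numbered 1892, against 644 for independent lists, both lower 1398 against 465, higher with H2O2 and lower in light 187 against 698, and lower with H2O2 and higher in light 158 against 429. Both responses are set against the same 2 dark arrays. In 100 simulations of unchanged groups that shared a dark group, a mean of 0.42 probe sets was called in both in the same direction. With no probe set changed, few pass the adjusted threshold by construction. That count is therefore no baseline for the 3290 found here. The log2 changes correlated across genes at r = 0.48 against a simulated 0.50, and their covariance was 0.242 against 0.0139. A split would leave a single dark array for each response and was not run, so part of the excess over independent lists may come from sharing the dark arrays. Without dark replicate 1, dark replicate 2, H2O2 replicate 1 or H2O2 replicate 2 the count in the same direction was 2299, 1757, 1598 and 1697. Both lower numbered 812, 626, 533 and 550 in these fits, and the opposite direction 168, 107, 160 and 96. With the arrays centred on the hybridisation controls 1549 were higher in both, 19 lower in both and 17 opposite. The both-lower and opposite classes thus hold on the deposited scale and not with this centring, which also costs calls through the spread it adds.

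**Figure D3:**
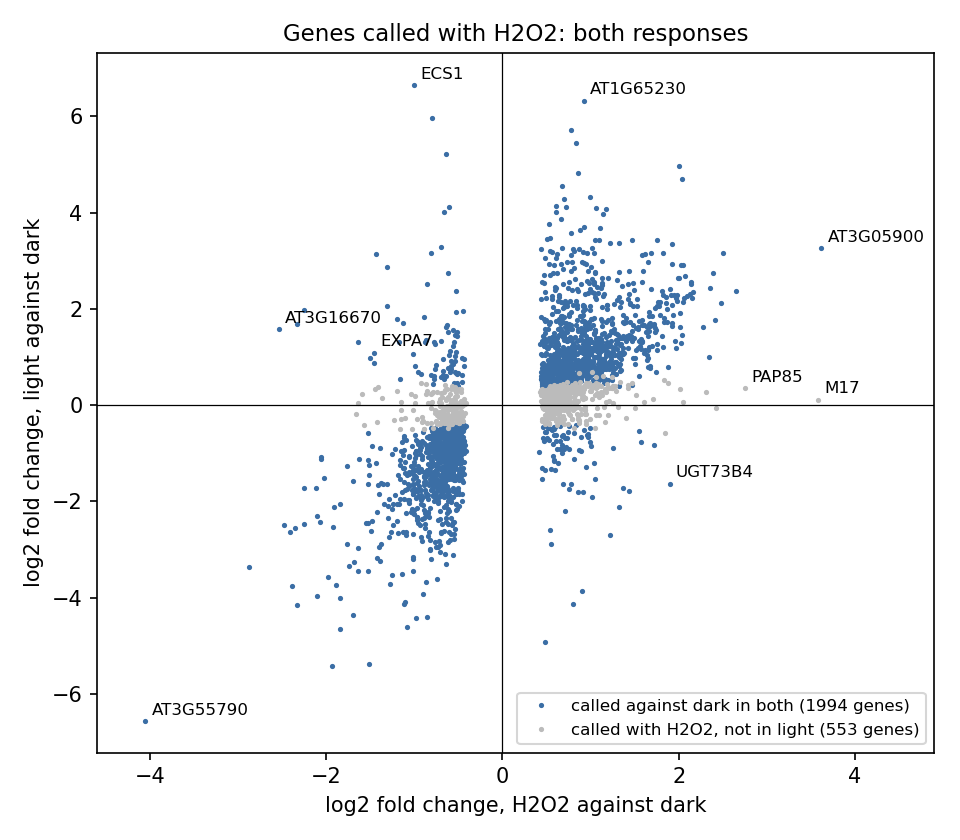
Log2 fold changes of 2547 genes called with H2O2 against dark (horizontal axis) set against their log2 fold changes in light against dark (vertical axis), one point per gene. Blue points (1994 genes) were called in both comparisons, 1012 of them higher in both and 820 lower in both, and grey points (553 genes) were not called in light.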

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

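Every count of calls stayed within 1.5 times its value with the replicate block, the trended and robust prior and the fit of the compared groups alone. With cyclic loess the H2O2 gene lists called rose from 2 to 5, and without the dimmest 40% of probe sets they fell to 0. Without these probe sets the lists called in light fell from 9 to 6. The causes were not tested. At an adjusted p under 0.01, 2109 probe sets were called with H2O2 and 1550 in the overlap, with 87 in opposite directions. With 1 probe set per gene, which tests fewer by construction, 2520, 5804 and 4630 were called with H2O2, in light and between light and H2O2. With an estimated correlation 0 lists were called with H2O2 and 0 in light. Centring on the hybridisation controls left 2379, 5261 and 2576 calls and an overlap of 1568 with 17 in opposite directions, and reversed the H2O2 changes of AT4G36430 (0.20), AT5G38980 (0.12), EXPA20 (0.16), AT1G22690 (0.13), AT1G05340 (0.22) and AT2G29310 (0.17), and the medians of the oxidative stress markers (0.25), expansins (0.55) and class III peroxidases (0.34). Against other genes camera set these 3 lists lower, at adjusted p = 0.00391, 0.0293 and 0.000956, so that the oxidative stress marker and expansin calls were gained, while the heat shock call with H2O2 ended (0.0607). That shift of the whole scale moved these signs by its construction. Centring also added the replicate differences of the controls, 0.668 between the dark and 0.864 between the light arrays, to every probe set. Calls can therefore be lost by construction too. The shifts of the median against dark, 0.778 with H2O2 and 0.689 in light, were about as large as these replicate differences. The changes of sign rest on shifts of that size. Between light and H2O2 the median moved by only -0.089, while the calls fell from 8981 to 2576. Which scale is right was not tested.

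Leaving out 1 array at a time gave 2135 to 4949 calls with H2O2, 9315 to 10468 in light, 6797 to 8843 between light and H2O2, 1598 to 3279 in the overlap, 0 to 3 lists with H2O2 and 9 lists in light; a lone array was assumed to vary like the other groups. Of the named genes, 38 of 66 called with H2O2, 105 of 108 in light and 93 of 98 between both stayed called in every such fit. A call can end in such a fit from lost power alone, since a compared group may then hold a lone array. With centring on the hybridisation controls 38, 98 and 87 of the same named calls stayed called. Across all probe sets the replicate number shared between groups showed no pairing: deviations from the group means correlated at -0.032, 0.069 and -0.0019. The replicate block gave 4590, 10905 and 8972 calls, with lists 3 and 9 and an overlap of 3243. Replicate 2 had the higher 3-prime signal in each group, by 0.233 in the dark, 0.162 with H2O2 and 0.254 in light. A shared replicate effect of that kind stays possible. Removing the trend on gene span, chosen after seeing the data, left 2252 of 2510 calls with H2O2 in number and 2052 in common. Signal over background limits the dim probe sets.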

Other observations

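The gene groups here, and their fits without each array, were chosen after seeing the data. Of 38 families sharing a symbol stem, 7 were called by camera with H2O2 and 1 in light. These tests took no account of gene span, which went with the H2O2 change (rank correlation 0.269). Whether the family calls follow from the spans of their members was not tested. Of 5 other sets, the mitochondrial genome and the 3 seed sets below were called with H2O2; these 3 overlap, and 1 holds members whose rises had been seen before. The plastid and mitochondrial genomes were called in light. Over all 43 sets, 0 were called with an estimated correlation (adjusted p 0.541 or more with H2O2 and 0.91 or more in light). That test had little power here, as it had for the lists. Of 69 plastid genome transcripts, 16 were called higher with H2O2 and 0 lower, without the set passing the test (adjusted p = 0.0755), and 31 were higher in light (adjusted p = 9.21e-06). The 2 dark arrays differ on these transcripts: 28 of the 69 lie over 2-fold apart, 26 of them higher on dark replicate 1, against 0.523% of all probe sets and 0 plastid transcripts between the H2O2 arrays. Between the light arrays 11 (15.9%) lie that far apart, all higher on light replicate 2. Without dark replicate 2, 12 were higher and 11 lower with H2O2, and 30 higher and 11 lower in light. Without dark replicate 1, 25 and 42 were higher and 0 lower. Without H2O2 replicate 1 or 2, 6 and 8 were higher with H2O2. Without light replicate 2, 24 were higher and 1 lower in light, and the median of 0.60 became 0.28. The plastid set therefore has no settled direction with H2O2. Most of its members that differed between replicates differed the same way, in the dark and in light. The preset correlation may therefore make its camera p-values too small. The call of the set in light is not settled by them. Among single genes, rps3 at 1.48 ± 0.20, psbE at 0.93 ± 0.14 and psbF at 0.85 ± 0.14 stayed called without any array.

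The mitochondrial genome set was taken by symbols starting with nad, cox, ccb, matR or orfX, so other genes of that genome are left out. Of its 16 transcripts, 7 were lower and 1 higher with H2O2 (camera adjusted p = 0.00569). Their median of -0.53 turned to 0.25 with centring on the hybridisation controls. In light 11 were lower (camera adjusted p = 0.0123). The calls with H2O2 included cox1 at -1.01 ± 0.21, cox2 at -0.89 ± 0.18 and ccb382 at 1.66 ± 0.15. Without dark replicate 2, H2O2 replicate 1 or H2O2 replicate 2, 3, 1 and 3 were lower, where cox1 (adjusted p 0.0517 to 0.0865) was not called, nor cox2 without H2O2 replicate 1 (0.0756).

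Of 11 PRA genes, encoding prenylated Rab acceptors of membrane trafficking, 7 were lower with H2O2 and 0 higher (adjusted p = 0.00107), at a median of -0.62 that turned to 0.16 with centring on the hybridisation controls, with PRA8 at -0.92 ± 0.16. Of these 11, 9 were lower in light (adjusted p = 0.0019). Without dark replicate 2 or H2O2 replicate 1, 4 and 3 PRA genes were lower with H2O2. Of 15 IQD genes, encoding calmodulin-binding proteins, 5 were higher with H2O2 and 0 lower (adjusted p = 0.00253), with iqd32 at 1.97 ± 0.22, and 3 without either H2O2 replicate. Of 10 NET genes, encoding actin-binding proteins, 4 were higher (adjusted p = 0.00803), with NET4B at 1.13 ± 0.16, and 2 without dark replicate 2. The other families called with H2O2 were CHR (3 of 8 higher, adjusted p = 0.03, with CHR17 at 1.26 ± 0.29), TRM (4 of 15 higher, 0.03, with TRM19 at 1.08 ± 0.18), CML (2 of 7 lower, 0.0321, with CML43 at -1.25 ± 0.20) and LSM (2 of 6 lower, 0.0464, with LSM6B at -0.66 ± 0.13). The medians of CML and LSM turned from -0.31 to 0.47 and from -0.41 to 0.37 with the same centring. In the fits without 1 array, 1 to 3 CHR and 1 to 4 TRM genes were called higher, and 1 to 3 CML and 0 to 2 LSM genes lower. CHR17 ended without dark replicate 2 or either H2O2 replicate (0.0524 to 0.123), and LSM6B without H2O2 replicate 2 (0.0612).

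The gene span pattern was tested with predictions written before each result, except that the comparison of single pairs of arrays was chosen after the result was seen. Longer genes lay higher with H2O2 (rank correlation 0.269). A 3-prime bias of the labelled RNA could give such a trend, but H2O2 and dark differed by only 0.0076 in 3-prime signal. Every replicate pair differed by more, from 0.162 to 0.254, so the condition of at least the same shift left none out. The largest trend among them was -0.126. That is close to the bound set beforehand, 50% of the H2O2 trend, and does not decide the question alone. The 2 pairs in which the H2O2 array had the higher 3-prime signal still had 0.218 or more. Both use dark replicate 1, so they are not separate evidence. Brightness of the hybridisation could also give the trend. Replicate pairs with at least 50% of the shift of the hybridisation controls between H2O2 and dark reached only -0.071. Their sign goes with brightness, since their controls rose by 0.668 and 0.864 where those with H2O2 against dark fell by 0.778. The size of their trend falls short. Mean signal is argued against for brighter probe sets, since the lowest value in the brighter 3 of 5 groups by mean signal was 0.327. The dimmer groups had 0.029 and 0.194. An effect of H2O2 on longer genes stays open, as the design gives it and no test here bears on it; in light a 3-prime shift of -0.183 keeps 3-prime bias open too.

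The seed pattern was tested with predictions written before the results, except the counts without an array. Storage protein and late embryogenesis transcripts were higher with H2O2, with a median log2 change of 2.37 over the 6 members seen before. A wider seed maturation programme is in line with the 21 members not seen before, of which 17 lay higher, 7 were called (2 to 6 without any 1 array) and the median was 0.43 (camera p = 5.89e-05), though none of these sets was called with an estimated correlation. Seeds that had not germinated among the harvested seedlings might also raise these transcripts: the median over the 11 brighter unseen members was 0.581, with members from -0.030 to 2.02 and a 95% bootstrap interval of 0.146 to 1.70. The bound set for that test, 0.592, was taken from the members seen before, of which M17, PAP85 and AT2G28490 were among the largest rises, and 24 of all 27 members are dim in the dark, so it decides nothing. Ungerminated seeds and the wider programme cannot be told apart here, since that bound and the spread between members leave both open.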
